A study of Mus musculus with 6 samples.

How the data were processed

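Gene expression was measured by RNA sequencing in quadriceps muscle of mouse pups at postnatal day 10, in 3 control libraries (Pcyt2 flox/flox) and 3 Myf5Cre-Pcyt2 libraries. Per the labels, the muscles were frozen in liquid nitrogen, RNA was purified with an RNeasy column kit, and 1.3 µg of total RNA went into each library. The deposited values are counts per Ensembl gene, which the authors made, per the submitters' processing notes, with Trim Galore 0.5.0, Bowtie2 2.3.4.1 and featureCounts of Subread 1.6.2 on GRCm38/mm10. The notes list these tools without role or order. The annotation release, the strand setting, the handling of reads that map to several places, and the sequencing layout are not given in the sources used here. Genes that share sequence with paralogs or pseudogenes therefore have uncertain counts, and this applies to the myosin heavy chains, ribosomal proteins, Eno1b and overlapping transcripts such as H19.

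The count table held 54532 genes, of which 54409 were given a symbol and 54495 a position from GENCODE M21. No count column was left out. A total of 26363 genes had 0 counts in every library. Library totals lay between 17775898 and 20446920 counts, and intervals cover counting error and the spread between these libraries only. Xist and Y-linked counts showed replicate 3 of each group to be male and the others female. The labels do not state whether the pups came from separate litters, so p-values measure the spread between these 6 libraries. No pair of libraries looked like a copy of another, and libraries with the same replicate number were no closer to each other than other pairs, so no pairing was used.

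Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Genes were filtered with edgeR's filterByExpr on the group, which kept 14715 genes, and libraries were scaled with TMM factors. The groups were compared with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 on the adjusted p. Log2 fold changes are Myf5Cre-Pcyt2 over control, so negative values are lower in Myf5Cre-Pcyt2, and their errors are standard errors (SE) from the fit. Expression levels are TMM-normalised CPM (counts relative to the scaled library total), given as mean ± SD with n = 3 per group. Library size alone shifted the median of all genes by 0.21 on the log2 scale relative to TMM, and all changes are given relative to TMM.

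Gene lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 36 lists with at least 3 tested members. Camera with an estimated correlation and limma's fry were run beside it. Fry asks whether the genes of a list move, on balance, in a single direction, and compares no list with other genes. The neutrophil and lymphocyte list had too few tested members, and the sex-linked list served only to check the animals. Shares of myosin heavy chain counts were compared with an exact permutation test, two-sided, for which the smallest p with 3 against 3 libraries is 0.1.

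The lists, the tests, the rule for named genes and the alternatives not named as added were chosen before the data were examined. The rule named Pcyt2 and Myf5, then the 10 largest rises and the 10 largest falls among genes past the threshold with non-overlapping groups and a mean of at least 1 CPM, without unnamed gene models and pseudogenes. It also named up to 3 members with the smallest p of each list past the threshold, and at most 1 member of each other list. The rule also selected 1 gene that is not reported here, which stays in the totals and list counts. Genes outside this rule are said to have been chosen after their values were seen.

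The procedure was tested on simulated negative binomial counts of 14503 genes with 200 changed genes. It recovered 53.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, and 12 of its 176 calls had no simulated change. In the simulated lists, 1 of 1 shifted list was found. The simulated genes varied independently of each other, so this does not measure false list calls where the genes of a list vary together. The estimated biological coefficient of variation of the measured libraries was 11.6%, and the smallest log2 change called had a size of 0.247.

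The alternatives were DESeq2 size factors, library size alone, DESeq2, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, leaving out mitochondrially encoded genes, a replicate block, a covariate for sex, and leaving out each library in turn. Alternatives added after the data were seen left out 96 genes of 6 lists of other cell types, the 20 most abundant genes, or 489 tested genes within 20 Mb of Pcyt2 or Myf5. Others added then used an offset for GC content and gene length (loess, span 0.5), alone and with the replicate block.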

Results

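Muscle of Myf5Cre-Pcyt2 pups had high levels of several neonatal muscle transcripts and low levels of adult fast-fibre and energy-metabolism transcripts compared with control muscle. The neonatal myosin heavy chain gene Myh8 rose from 789 ± 441 to 6481 ± 2069 CPM (SD, n = 3 per group). The imprinted growth gene Dlk1 rose from 221 ± 58.7 to 838 ± 215 CPM, and the fast myosin-binding protein gene Mybpc2 fell from 7201 ± 1977 to 3239 ± 686 CPM. Of 76 tested nuclear genes of oxidative phosphorylation, 53 fell and 0 rose, and the 53 were 31, 14 and 18 without control replicate 3, Myf5Cre-Pcyt2 replicate 2 and Myf5Cre-Pcyt2 replicate 3, and 18 with library size alone as the scaling. With camera and a preset correlation between genes 16 of 36 lists passed, 0 passed with an estimated correlation (smallest adjusted p 0.436, 2 lists at an unadjusted p under 0.05), and 15 passed with fry. Splits of the libraries that mixed the groups still passed 4 to 15 lists with the preset correlation. Those splits kept part of the group difference, so they do not measure false list calls.

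The data are RNA sequencing counts of quadriceps from P10 pups on chow, with 3 control pups' libraries (Pcyt2 flox/flox) and 3 Myf5Cre-Pcyt2 libraries, in which Cre is driven from Myf5 in muscle precursors. Per the labels the series asks how loss of Pcyt2 alters gene expression in developing muscle. The controls are not said to carry Cre, so effects of Pcyt2 loss and of Cre driven from Myf5 cannot be told apart. The control libraries held 19546795, 20216013 and 17775898 counts. The Myf5Cre-Pcyt2 libraries held 18271765, 20446920 and 20038248 counts. Between 20921 and 23122 genes were detected per library. The 10 most abundant genes took 22, 25.6 and 21.1% of counts in control and 19.3, 16.2 and 17.1% in Myf5Cre-Pcyt2. The leading principal component carried 52.5% of the variance and separated the groups, with scores of −17.39, −40.62 and −19.28 in control and 17.61, 35.53 and 24.16 in Myf5Cre-Pcyt2.

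Pcyt2 (ENSMUSG00000025137, protein coding, GRCm38 chromosome 11, 120610087 to 120617936) encodes the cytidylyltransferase that makes CDP-ethanolamine for phosphatidylethanolamine synthesis. Its counts were 353, 277 and 277 in control and 280, 328 and 272 in Myf5Cre-Pcyt2. The level was 16.9 ± 1.52 CPM in control and 13.9 ± 1.24 CPM in Myf5Cre-Pcyt2, a log2 fold change of −0.28 (SE 0.11) that did not pass the threshold (adjusted p = 0.0944). This left 82.3% of the control level (95% interval 69.6 to 97.2%). The adjusted p ranged from 0.0421 to 0.706 over 19 alternatives, and the lowest came from an offset for GC content and gene length. The deleted part of the gene is not given in the sources used here, so a count per gene does not show how much of the intact transcript is left. Myf5 (ENSMUSG00000000435, chromosome 10, 107482908 to 107486134), a myogenic regulator, had 4.71 ± 0.922 CPM in control and 5.18 ± 0.337 CPM in Myf5Cre-Pcyt2, with a log2 fold change of 0.13 (SE 0.18, adjusted p = 0.633). Its counts were 107, 80 and 66 against 99, 110 and 118. Of the 5 tested genes of the ethanolamine branch of the Kennedy pathway, Pcyt2 included, 0 passed the gene threshold, and 0 passed adjusted over the list alone. Selenoi, which encodes the final enzyme of that branch, had a log2 fold change of 0.26 (SE 0.08, adjusted p = 0.0555), and passed with library size alone (0.0157) and with the filter of 1 CPM in 3 libraries (0.0499), over a range of 0.0157 to 0.32. The list had a median of −0.19 and a camera adjusted p of 0.597.

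Of 14715 genes tested, 2739 (18.6%) differed between the groups, with 1328 higher and 1411 lower in Myf5Cre-Pcyt2. At least a 2-fold difference was reached by 244 higher and 166 lower genes, 410 in all. Control and Myf5Cre-Pcyt2 ranges did not overlap for 5745 genes (39%), where chance gives 10%. The number of changed genes was 1300 without control replicate 2, 846 without Myf5Cre-Pcyt2 replicate 2 and 1280 without Myf5Cre-Pcyt2 replicate 3, and between 2181 and 2785 without any of the other libraries. The higher genes were then 601, 422 and 639, and the lower genes 699, 424 and 641. Without control replicate 2 and Myf5Cre-Pcyt2 replicate 2 in turn, 240 and 187 genes reached 2-fold. With library size alone as the scaling, 86.6% of 3724 changed genes were higher, against 48.5% with TMM.

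**Figure D1:**
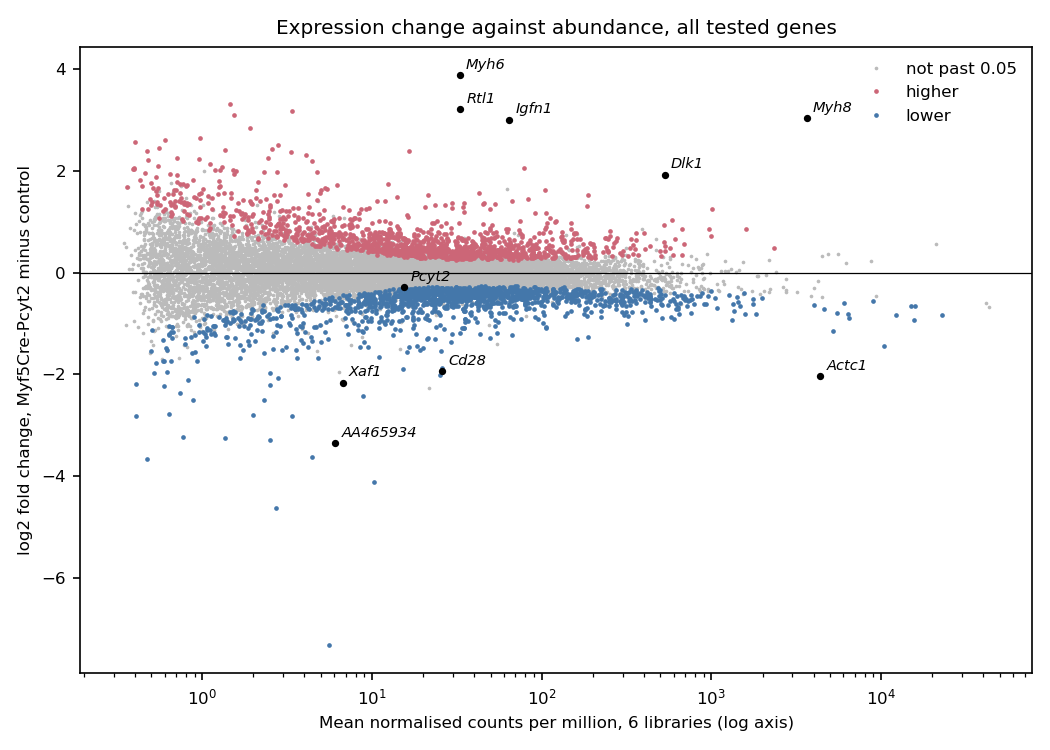
Log2 fold change of Myf5Cre-Pcyt2 over control for the 14715 tested genes (vertical axis) against their mean normalised CPM in the 6 libraries (log axis). Points in red are the 1328 higher genes, points in blue the 1411 lower genes, and points in grey the genes that did not pass the threshold, with Pcyt2 at −0.28.

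The largest rises included genes of immature or cardiac muscle. Myh8 (chromosome 11, 67277124 to 67308634) rose by a log2 change of 3.04 (SE 0.43, adjusted p = 0.00306). Myh6, the cardiac alpha myosin heavy chain gene, rose from 4.20 ± 1.01 to 61.6 ± 50.3 CPM (log2 fold change 3.87, SE 0.69, adjusted p = 0.0061), with counts of 178, 2514 and 1421 in the Myf5Cre-Pcyt2 libraries. With limma-voom the adjusted p of Myh6 was 0.0540, the highest over 20 alternatives, of which the lowest was 1.32e-186. Rtl1, an imprinted retrotransposon-derived gene (chromosome 12, 109589193 to 109600330), rose from 6.42 ± 5.39 to 59.5 ± 19.7 CPM. Igfn1, an immunoglobulin-like fibronectin gene of skeletal muscle, rose from 14.2 ± 7.84 to 114 ± 33.7 CPM (log2 fold change 3.01, SE 0.38, adjusted p = 0.00193). Further large rises by the rule were Tmem72, Mtus2, Habp2, Pla2g5 and Ptprv, with log2 changes from 2.19 to 3.10.

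Actc1, the cardiac alpha-actin gene expressed in fetal and newborn skeletal muscle (chromosome 2, 114047282 to 114053548), fell from 7019 ± 2795 to 1722 ± 443 CPM (log2 fold change −2.03, SE 0.28, adjusted p = 0.00288). AA465934, a transcript without a named product, fell from 11.1 ± 1.95 to 1.08 ± 0.309 CPM (−3.35, SE 0.23, adjusted p = 7.09e-05). The interferon-induced gene Xaf1 (chromosome 11, 72301629 to 72313733) fell from 11 ± 0.715 to 2.45 ± 0.0462 CPM, and the T-cell costimulatory receptor gene Cd28 fell from 41.0 ± 9.24 to 10.8 ± 3.82 CPM. Eno1b, whose counts are uncertain because its sequence is close to that of Eno1, had counts of 114, 114 and 88 in control and 1, 1 and 51 in Myf5Cre-Pcyt2 (−2.82, SE 0.72, adjusted p = 0.0234). It did not pass without control replicate 2 (0.0662), without Myf5Cre-Pcyt2 replicate 2 (0.0754) or with DESeq2 (0.191), over alternatives that reached down to 3.36e-28. Its log2 fold change ranged from −6.76 to −2.24 over the alternatives. Ifitm10 (−1.68, SE 0.36, adjusted p = 0.0126) did not pass without Myf5Cre-Pcyt2 replicate 2 (0.0648, range over alternatives 3.62e-07 to 0.0648). The other large falls by the rule were Cntn1, Retnla, Cib2 and Neu2, with log2 changes from −2.21 to −1.67.

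The developmental contractile list holds sarcomere genes, acetylcholine receptor subunits, Ncam1 and 6 imprinted growth genes of immature muscle. Of its 17 tested genes, 13 rose, 1 fell and 3 did not pass, and 15 were higher and 1 lower adjusted over the list alone. The list median was 0.78 (camera adjusted p = 5.09e-07; adjusted p = 0.469 with an estimated correlation). Its members with the smallest p were Ncam1 at 0.78 (SE 0.09, adjusted p = 0.00136), Dlk1 at 1.93 (SE 0.22, adjusted p = 0.00142) and Myh8. Actc1 was the member that fell. Among the 7 sarcomere genes of the list, a subset chosen after their values were seen, 4 rose, 1 fell and 2 did not pass (median 0.79), and the 4 became 2 without Myf5Cre-Pcyt2 replicate 2. Without control replicate 3, 6 rose and 1 fell (median 1.28), and with no filter 6 rose and 1 fell (median 0.79). The embryonic myosin gene Myh3, also chosen after its values were seen, rose from 50.9 ± 16.2 to 157 ± 47.4 CPM. Without Myf5Cre-Pcyt2 replicate 2, 8 of the 17 members were higher. As a share of the counts of Myh1, Myh2, Myh3, Myh4, Myh7 and Myh8, Myh8 took 1.36 ± 0.893% in control and 13.5 ± 6.7% in Myf5Cre-Pcyt2, and the adult fast isoform Myh4 took 83.1 ± 4.44% and 64.7 ± 6.6%. Both comparisons gave p = 0.1 in an exact permutation test, two-sided, the smallest p possible with n = 3 per group. The Myh1 share was 13 ± 2.92% and 18.5 ± 1.06% (exact permutation test, p = 0.1). Myosin heavy chain genes share sequence, so the split between them is uncertain.

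Of 18 fast-fibre genes tested, 11 fell, 1 rose and 6 did not pass, with 16 lower and 1 higher adjusted over the list alone (median −0.66, camera adjusted p = 1.90e-06; adjusted p = 0.469 with an estimated correlation). Mybpc2 fell with a log2 fold change of −1.15 (SE 0.22, adjusted p = 0.00779), and Pgam2, the muscle phosphoglycerate mutase gene, with −0.81 (SE 0.13, adjusted p = 0.00473). Pgam2 did not pass with the replicate block beside the GC content and length offset (0.0545, range over alternatives 1.5e-10 to 0.0545). Myh13, the superfast myosin gene in the same list, rose with 0.98 (SE 0.17, adjusted p = 0.006). The number of lower fast-fibre genes was 7, 3 and 3 without control replicate 2, Myf5Cre-Pcyt2 replicate 2 and Myf5Cre-Pcyt2 replicate 3. Of 15 slow-fibre genes, 5 rose, 0 fell and 10 did not pass, with 6 higher adjusted over the list alone (median 0.69, camera adjusted p = 1.09e-04; adjusted p = 0.503 with an estimated correlation). Myh7b rose with 1.06 (SE 0.15, adjusted p = 0.00292). Ankrd2 and Casq2 rose with 1.25 and 0.93 (SE 0.28 and 0.22, adjusted p = 0.0134 and 0.0178). Ankrd2 did not pass without control replicate 2 (0.0520) or Myf5Cre-Pcyt2 replicate 2 (0.0643), over alternatives that reached down to 1.2e-28, and Casq2 did not pass without Myf5Cre-Pcyt2 replicate 2 (0.0639, range over alternatives 1.01e-13 to 0.0639). With fry the slow-fibre list did not pass (0.109, range over alternatives 6.75e-10 to 0.503). The number of higher slow-fibre genes was 3, 2, 14, 1 and 3 without control replicates 1, 2 and 3 and Myf5Cre-Pcyt2 replicates 2 and 3. It was 8 with library size alone, with the replicate block with and without the GC content and length offset, and with a covariate for sex, and 13 with no filter. Lower fast-fibre genes numbered 7 with a covariate for sex, 3 with the replicate block and 2 with the block beside that offset. In the same libraries the Schwann cell and extracellular matrix lists were higher, with medians of 0.51 and 0.42 (adjusted p = 0.469 for each with an estimated correlation).

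Of 76 nuclear oxidative phosphorylation genes, 53 fell, 0 rose and 23 did not pass, with 72 lower adjusted over the list alone (median −0.43, camera adjusted p = 8.05e-19; adjusted p = 0.469 with an estimated correlation). The muscle cytochrome c oxidase subunit gene Cox6a2 fell from 773 ± 66.2 to 471 ± 20.4 CPM (log2 fold change −0.71, SE 0.10, adjusted p = 0.00341). Ndufs6 of complex I and Uqcrc1 of complex III fell with −0.56 (SE 0.09) and −0.66 (SE 0.11). Ndufs6 did not pass with the replicate block beside the GC content and length offset (0.053, range over alternatives 8.76e-07 to 0.053). The 53 became 31, 14 and 18 without control replicate 3 and Myf5Cre-Pcyt2 replicates 2 and 3. Of 13 mitochondrially encoded subunit genes in the count table, 7 passed the filter on low counts. All mitochondrially encoded genes together took only 0.344 to 0.529% of counts per library, and why was not tested. The list of these 7 had a median of −0.49 (camera adjusted p = 0.00603, or 0.503 with an estimated correlation). Of the 7 subunit genes, 5 fell, 0 rose and 2 did not pass, with 6 lower adjusted over the list alone. Among them, mt-Nd5 fell with −0.52 (SE 0.12, adjusted p = 0.0159) and did not pass without Myf5Cre-Pcyt2 replicate 2 (0.0708), without Myf5Cre-Pcyt2 replicate 3 (0.0582), or with the replicate block alone (0.0532) or beside the GC content and length offset (0.0629, range over alternatives 6.52e-05 to 0.0708). With fry this list did not pass (0.0925, range over alternatives 0.000978 to 0.503). The count of 5 became 1, 1, 0 and 1 without control replicates 2 and 3 and Myf5Cre-Pcyt2 replicates 2 and 3. Of 21 tricarboxylic acid cycle genes, 15 fell, 0 rose and 6 did not pass, with 20 lower and 1 higher adjusted over the list alone (median −0.40, camera adjusted p = 5.44e-08; adjusted p = 0.469 with an estimated correlation). Suclg2, Sdhb and Mdh2 fell with −0.51, −0.57 and −0.62 (SE 0.09, 0.10 and 0.12). The count of 15 became 9, 4 and 6 without control replicate 2, Myf5Cre-Pcyt2 replicate 2 and Myf5Cre-Pcyt2 replicate 3. With library size alone as the scaling, 18 nuclear, 2 mitochondrially encoded and 5 tricarboxylic acid cycle genes were lower, and 1 of the latter was higher. With the replicate block these lower counts were 32, 1 and 5, with the block beside the GC content and length offset 17, 1 and 5, and with no filter on low counts 69 nuclear and 19 tricarboxylic acid cycle genes were lower.

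Of 24 genes of glycolysis and glycogen use, 13 fell, 0 rose and 11 did not pass, with 16 lower and 1 higher adjusted over the list alone (median −0.44, camera adjusted p = 7.01e-06; adjusted p = 0.469 with an estimated correlation). Pfkfb1, which sets the level of the activator of phosphofructokinase, fell with −1.14 (SE 0.14, adjusted p = 0.0017). Phkg1, the catalytic subunit of muscle phosphorylase kinase, fell with −0.85 (SE 0.15, adjusted p = 0.00576). The count of 13 became 7, 4 and 4 without control replicate 2, Myf5Cre-Pcyt2 replicate 2 and Myf5Cre-Pcyt2 replicate 3. Of 30 fatty acid oxidation genes, 6 fell, 1 rose and 23 did not pass, with 8 lower and 2 higher adjusted over the list alone (median −0.15, camera adjusted p = 0.0164; adjusted p = 0.621 with an estimated correlation). The mitochondrial acyl-CoA dehydrogenase gene Acadvl fell with −0.44 (SE 0.10, adjusted p = 0.0124), and Cpt1a, which encodes the liver form of the carnitine transferase for import, rose with 0.45 (SE 0.10, adjusted p = 0.0143). Without Myf5Cre-Pcyt2 replicate 2 neither passed (0.0609 and 0.0673), and Cpt1a did not pass without replicate 3 of that group (0.0536). Acadvl did not pass with library size alone (0.0831), and with the replicate block alone (0.053) or beside the GC content and length offset (0.063), and Cpt1a did not pass with the block beside that offset (0.0529). Over the alternatives their adjusted p ranged from 3.2e-05 to 0.0831 and from 4.3e-04 to 0.0673. With library size alone, 8 glycolysis genes were lower and 1 higher, and 0 fatty acid oxidation genes were lower and 3 higher, with a median of 0.05 for the latter list, which did not pass (0.128). With the replicate block, 5 glycolysis and 3 fatty acid oxidation genes were lower, and with the block beside the GC content and length offset 5 and 2. It did not pass with fry (0.109) or without Myf5Cre-Pcyt2 replicate 2 (0.1, range over alternatives 0.00238 to 0.621), and its count of 6 became 3, 0 and 3 without Myf5Cre-Pcyt2 replicates 1, 2 and 3.

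**Figure D2:**
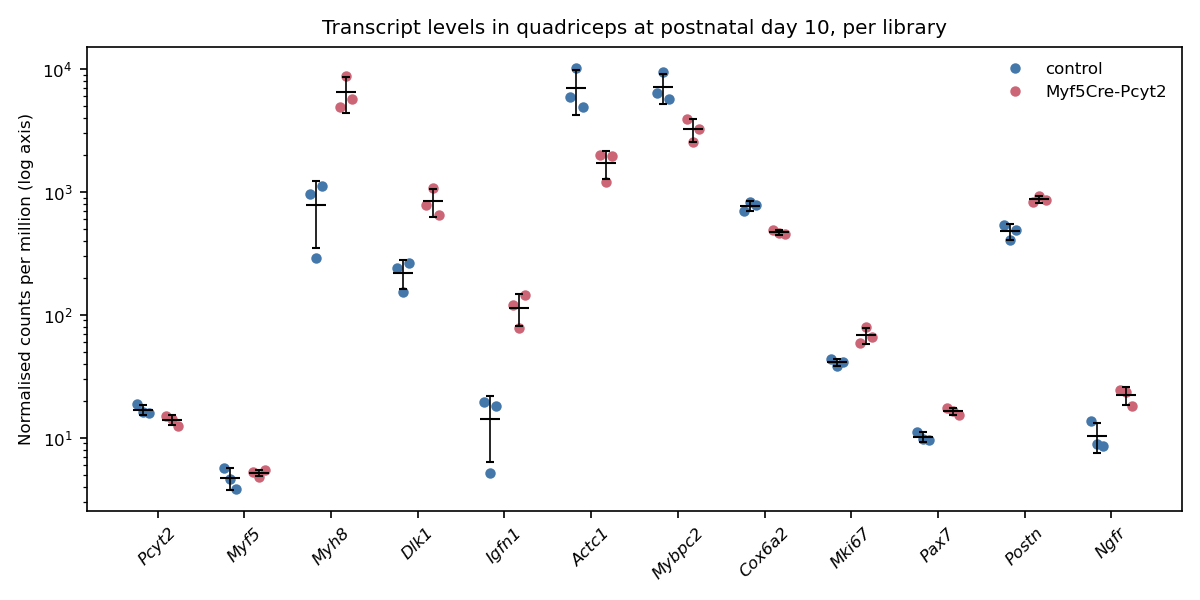
Normalised CPM of 12 genes in each library (points, log axis), with bars for the mean and SD of the 3 control and 3 Myf5Cre-Pcyt2 libraries. Myh8 rose from 789 to 6481 CPM on average and Cox6a2 fell from 773 to 471 CPM.

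Of 32 cell cycle genes, 16 rose and 16 did not pass, with 19 higher adjusted over the list alone (median 0.42, camera adjusted p = 1.08e-07; adjusted p = 0.469 with an estimated correlation). Mki67, a marker of dividing cells, rose from 41.3 ± 2.63 to 68.1 ± 10.6 CPM (log2 fold change 0.72, SE 0.11, adjusted p = 0.00416), and Mcm5 and Top2a rose with 0.61 and 0.55 (SE 0.11 and 0.10). The count of 16 became 10 with the replicate block, and 8, 6, 4 and 9 without control replicates 1 and 2 and Myf5Cre-Pcyt2 replicates 2 and 3. Of 16 satellite cell genes, 8 rose and 8 did not pass, with 9 higher adjusted over the list alone (median 0.28, camera adjusted p = 4.80e-05; adjusted p = 0.436 with an estimated correlation). The satellite cell regulator Pax7 rose from 10.2 ± 0.926 to 16.4 ± 1.18 CPM (0.69, SE 0.11, adjusted p = 0.00421), and the adhesion genes Cdh15 and Vcam1 rose with 0.78 and 0.76 (SE 0.09 and 0.10). The count of 8 became 5 without Myf5Cre-Pcyt2 replicate 2. Of 25 extracellular matrix genes, 14 rose and 11 did not pass, with 16 higher adjusted over the list alone (median 0.42, camera adjusted p = 1.07e-06; adjusted p = 0.469 with an estimated correlation). The matrix gene Postn rose from 479 ± 70.3 to 870 ± 50.5 CPM (0.86, SE 0.12, adjusted p = 0.00322), and the fibroblast receptor gene Pdgfra and the fibrillin gene Fbn1 rose with 0.54 and 0.65 (SE 0.08 and 0.11). The count of 14 became 8 with the replicate block beside the GC content and length offset, and 7 and 8 without Myf5Cre-Pcyt2 replicates 2 and 3. Of 13 Schwann cell and nerve genes, 6 rose and 7 did not pass, with 8 higher adjusted over the list alone (median 0.51, camera adjusted p = 2.28e-04; adjusted p = 0.469 with an estimated correlation). Ngfr, the neurotrophin receptor gene of immature Schwann cells, rose from 10.4 ± 2.83 to 22.1 ± 3.57 CPM (1.09, SE 0.18, adjusted p = 0.00467), and Sox10 and Prx rose with 0.92 and 0.64 (SE 0.16 and 0.13).

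Markers of other cells were measured in the same libraries and did not pass as lists, and with library size alone the endothelial and smooth muscle medians were above 0, at 0.15 and 0.18. That scaling gave 2 higher and 0 lower endothelial genes, 4 higher and 0 lower macrophage genes, 3 higher and 1 lower smooth muscle genes, 7 higher tendon genes and 2 higher erythroid genes. The endothelial list had 0 higher and 2 lower of 16 genes (median −0.06, camera adjusted p = 0.411; 2 lower adjusted over the list alone). The macrophage list had 0 higher and 1 lower of 20 (median 0.10, adjusted p = 0.593), and the smooth muscle list 1 higher and 1 lower of 12 (median −0.03, adjusted p = 0.82), where Acta2 fell with −0.81 (SE 0.17, adjusted p = 0.0117). The erythroid list had 1 higher of 9 (median 0.26, adjusted p = 0.292) and the keratinocyte list 0 of 3 (median 0.08, adjusted p = 0.869). Of 12 tendon and cartilage genes, 3 rose, among them Scx with 0.66 (SE 0.13, adjusted p = 0.00921). That list did not pass (median 0.30, adjusted p = 0.071) and passed without control replicate 2 (0.000535) and Myf5Cre-Pcyt2 replicate 1 (0.0347), over a range of 0.000535 to 0.708. The adipocyte list had 0 of 14 genes past the threshold (median −0.48, adjusted p = 0.593) and passed without control replicate 2 (median −0.92, adjusted p = 0.000437, range over alternatives 0.000437 to 0.918), a library with 5.51 CPM of the fat-cell gene Adipoq, chosen after its values were seen, against 50.2 and 17.9 CPM in the other control libraries. Without control replicate 1, 2 adipocyte genes were higher, and without control replicate 2, 5 were lower. With no filter on low counts, 10 of 15 adipocyte genes were lower and 1 was higher while the list did not pass, 4 macrophage genes were higher and 2 lower, and 6 tendon genes were higher. Leaving out control replicates 1, 2 and 3 and then Myf5Cre-Pcyt2 replicates 1, 2 and 3, the tendon list had 2, 5, 2, 5, 1 and 1 higher genes, with 1 lower without control replicate 3. In the same order, the endothelial list had 0, 0, 2, 0, 0 and 0 lower genes, and the macrophage list had 0, 0, 1, 1, 0 and 0 lower and 0, 0, 2, 2, 1 and 0 higher. The erythroid list had 0, 0, 2, 0, 1 and 0 higher, with 1 lower without control replicate 1, and the smooth muscle list had 1, 0, 0, 1, 0 and 0 higher and 2, 1, 1, 1, 1 and 1 lower. The macrophage (0.0358) and erythroid (0.0326) lists passed with the replicate block beside the GC content and length offset, over ranges of 0.0358 to 0.996 and 0.0326 to 0.623. With limma-voom (0.0355), without genes near Pcyt2 and Myf5 (0.049), and with the offset alone (0.0472) or with the block (0.0484), the tendon list passed.

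Of 29 genes of atrophy and denervation, 9 rose, 2 fell and 18 did not pass, with 11 higher and 2 lower adjusted over the list alone (median 0.23, camera adjusted p = 0.0054; adjusted p = 0.436 with an estimated correlation). Igfn1 and Ncam1 were among its members with the smallest p. Chosen after their values were seen, Prkab2 and Bnip3 were the 2 that fell, and the ubiquitin ligase genes Fbxo32 and Trim63 had log2 fold changes of −0.37 and −0.33 and did not pass (adjusted p = 0.175 and 0.114). Of 19 insulin-like growth factor genes, 6 rose, 2 fell and 11 did not pass, with 9 higher and 3 lower adjusted over the list alone (median 0.20, camera adjusted p = 0.0442; adjusted p = 0.469 with an estimated correlation). Igf1r and Igf2r rose with 0.61 and 0.51 (SE 0.09 and 0.09), and Igf2r did not pass with the replicate block beside the GC content and length offset (0.0553, range over alternatives 4.56e-06 to 0.0553). Igfbp5 and Ghr, chosen after their values were seen, were the 2 that fell. That list lost its call in most alternatives: without control replicate 3 (0.158), Myf5Cre-Pcyt2 replicate 1 (0.0675) or Myf5Cre-Pcyt2 replicate 3 (0.0722), with library size alone (0.0702), with no filter (0.0551), with a covariate for sex (0.0551), and without genes near Pcyt2 and Myf5 (0.0592). It also lost the call with the replicate block (0.0518), the GC content and length offset (0.0884) or both (0.0991), with a range over alternatives of 0.0183 to 0.469, and its count of 6 became 3, 2 and 3 without control replicate 2 and Myf5Cre-Pcyt2 replicates 2 and 3. Of 16 interferon genes, 3 fell, 1 rose and 12 did not pass, with 5 lower and 1 higher adjusted over the list alone (median −0.43, camera adjusted p = 0.00236; adjusted p = 0.469 with an estimated correlation). The ubiquitin-like modifier gene Isg15 fell with −1.23 (SE 0.36, adjusted p = 0.036, range over alternatives 0.00774 to 0.146). It did not pass without control replicates 1 and 3 (0.0899 and 0.102) or without Myf5Cre-Pcyt2 replicates 1, 2 and 3 (0.0744, 0.0687 and 0.128), nor with library size alone (0.0703), DESeq2 (0.0718), a covariate for sex (0.0538), the GC content and length offset (0.0743) or the replicate block alone (0.0758) or beside that offset (0.146). The count of 3 became 1, 1, 1, 0 and 0 without control replicates 1 and 2 and Myf5Cre-Pcyt2 replicates 1, 2 and 3. Of 47 cytosolic ribosomal protein genes, 4 fell and 43 did not pass, with 2 lower adjusted over the list alone (median −0.11, camera adjusted p = 0.0362; adjusted p = 0.709 with an estimated correlation). The ribosomal list did not pass without control replicate 3 (0.301), Myf5Cre-Pcyt2 replicate 2 (0.06) or Myf5Cre-Pcyt2 replicate 3 (0.141), and its range over alternatives was 0.00196 to 0.709. It did not pass with fry (0.37), with the GC content and length offset (median −0.0215, 0.554) or with that offset beside the replicate block (median −0.0367, 0.582). Its count of 4 became 1, 2, 7, 1 and 2 without control replicates 2 and 3 and Myf5Cre-Pcyt2 replicates 1, 2 and 3, and its counts are uncertain because ribosomal pseudogenes have like sequence. The ribosomal median was 0.10 with library size alone, with 1 gene lower and 2 higher. With that scaling, 18 atrophy and denervation genes were higher and 1 lower, 12 growth factor genes were higher and 0 lower, and 0 interferon genes were lower and 1 higher. The lower interferon genes were also 0 with a covariate for sex and with the replicate block, 1 with DESeq2 and 5 with no filter. The higher growth factor genes were 1 with the block beside the GC content and length offset. Lower ribosomal genes were 10 with no filter and 0 with the block beside that offset. The 2 lower genes of atrophy and denervation became 1 without control replicate 2 and without Myf5Cre-Pcyt2 replicate 2. The 2 lower growth factor genes became 0, 0, 1, 1, 0 and 0 without control replicates 1, 2 and 3 and Myf5Cre-Pcyt2 replicates 1, 2 and 3.

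**Figure D3:**
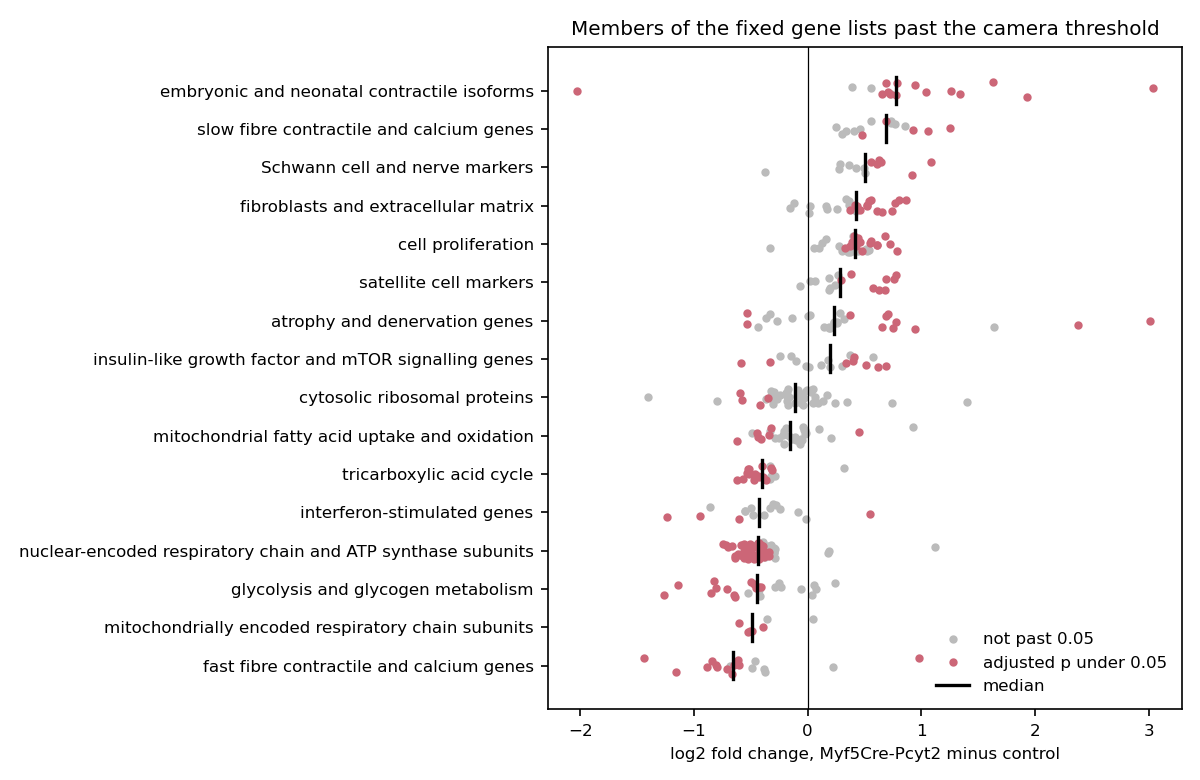
Log2 fold changes of the members of the 16 lists past the camera threshold, with a point per gene, red where the gene passed the threshold of 0.05, and a black bar at the list median. Medians run from −0.66 for fast-fibre genes to 0.78 for developmental contractile genes.

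Lists of lipid synthesis did not pass as lists, and with library size alone the medians of the ethanolamine, phosphatidylcholine and triacylglycerol lists were above 0, at 0.01, 0.09 and 0.0043. Phosphatidylcholine and phosphatidylserine synthesis had 0 higher and 1 lower of 12 genes (median −0.12, camera adjusted p = 0.135; 1 lower adjusted over the list alone), and Chpt1, a cholinephosphotransferase gene, was the member that fell (log2 fold change −0.64, SE 0.12, adjusted p = 0.00632). Diacylglycerol and triacylglycerol turnover had 2 higher and 4 lower of 24 (median −0.22, adjusted p = 0.109), with Agpat1 lower at −0.52 (SE 0.09, adjusted p = 0.00469). With library size alone, 3 genes of that list were higher and 1 lower, and with no filter 2 were higher and 7 lower of 25. Cholesterol synthesis had 3 higher and 2 lower of 22 (median 0.11, adjusted p = 0.465), with 6 higher and 3 lower adjusted over the list alone, and with 8 higher and 0 lower with library size alone. Fatty acid synthesis had 2 higher and 3 lower of 19 (median 0.07, adjusted p = 0.844), with 4 higher and 1 lower with library size alone and its carbohydrate-responsive regulator Mlxipl lower at −0.60 (SE 0.12, adjusted p = 0.00828). The triacylglycerol list passed without control replicate 2 (0.0291), with no filter (0.0447), and with the GC content and length offset alone (0.0414) or with the replicate block (0.0326), over a range of 0.0291 to 0.708. The phosphatidylcholine list passed with fry (0.0493) and with that offset alone (0.0488), over a range of 0.0488 to 0.503. Leaving out control replicates 1, 2 and 3 and then Myf5Cre-Pcyt2 replicates 1, 2 and 3, the triacylglycerol list had 2, 4, 5, 2, 1 and 3 lower and 2, 1, 2, 2, 1 and 1 higher genes. In the same order, fatty acid synthesis had 1, 3, 2, 2, 1 and 2 lower and 3, 0, 1, 0, 1 and 0 higher, cholesterol synthesis 2, 1, 1, 1, 0 and 0 lower and 1, 0, 7, 0, 0 and 1 higher, and phosphatidylcholine synthesis 1 lower each time except 2 without Myf5Cre-Pcyt2 replicate 1.

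Stress, repair and regulatory lists did not pass either, and with library size alone the medians of the integrated stress response, p53, antioxidant, immediate early and proteasome lists were above 0, at 0.18, 0.18, 0.04, 0.04 and 0.18. The integrated stress response list had 4 higher and 3 lower of 26 genes (median −0.03, camera adjusted p = 0.82), and the amino acid transporter gene Slc7a5 rose with 0.85 (SE 0.10, adjusted p = 0.00164). The unfolded protein response list had 1 higher and 1 lower of 23 (median 0.10, adjusted p = 0.0916), with 0 adjusted over the list alone. It passed with library size alone (median 0.31, adjusted p = 0.0358, 12 higher and 0 lower), with fry (0.025), and with the GC content and length offset alone (0.0194) or with the replicate block (0.0388), over a range of 0.0194 to 0.469. The p53 list had 3 higher and 3 lower of 17 (median −0.04, adjusted p = 0.869), with the regulator gene Ddit4l lower at −0.77 (SE 0.11, adjusted p = 0.00341). The NRF2 and antioxidant list had 1 higher and 4 lower of 21 (median −0.17, adjusted p = 0.0777), with the mitochondrial superoxide dismutase gene Sod2 lower at −0.55 (SE 0.10, adjusted p = 0.00615). The immediate early list had 0 higher and 5 lower of 20 (median −0.17, adjusted p = 0.292), with the phosphatase gene Dusp1 lower at −1.29 (SE 0.19, adjusted p = 0.0031). The proteasome list had 1 higher of 31 (median −0.03, adjusted p = 0.628). The membrane repair and dystrophin complex list had 3 higher and 5 lower of 25, with a median of 0.04, a mean of −0.06 and a test direction of lower (adjusted p = 0.827), and its filamin gene Flnc rose with 0.71 (SE 0.11, adjusted p = 0.00417). The list of myogenic regulators had 5 higher and 0 lower of 18 (median 0.12, adjusted p = 0.0807), and the 5 became 2 without control replicates 1 and 2 and 2 without each of the 3 Myf5Cre-Pcyt2 libraries. This list passed without control replicate 2 (0.0385), with limma-voom (0.0487), with fry (0.025) and without genes near Pcyt2 and Myf5 (0.0495), over a range of 0.025 to 0.469. The antioxidant list passed without control replicate 2 (0.0288) and with no filter (0.0204), over a range of 0.0204 to 0.503.

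The member counts of these lists moved with single libraries. Leaving out control replicates 1, 2 and 3 and then Myf5Cre-Pcyt2 replicates 1, 2 and 3, the immediate early list had 5, 1, 5, 4, 1 and 1 lower genes, with 1 higher without control replicate 3 alone. In the same order, membrane repair had 5, 3, 4, 7, 1 and 2 lower and 3, 2, 2, 2, 1 and 1 higher, and the antioxidant list had 2, 1, 4, 4, 1 and 2 lower. The integrated stress response list had 3, 1, 3, 4, 1 and 1 lower and 4, 2, 3, 2, 1 and 2 higher, and the p53 list had 3, 3, 3, 2, 2 and 2 lower and 2, 2, 3, 3, 1 and 1 higher. The unfolded protein response list had 1, 0, 0, 0, 0 and 0 lower and 0, 0, 1, 0, 0 and 0 higher, and the proteasome list had 0, 0, 0, 1, 0 and 0 lower and 0, 0, 1, 0, 0 and 0 higher. With library size alone, 2 immediate early, 2 membrane repair and 2 antioxidant genes were lower, and 9 myogenic regulators were higher, with 6 higher genes each in the p53, membrane repair and integrated stress response lists. The replicate block gave 1 lower membrane repair gene and 2 higher myogenic regulators, and with no filter 8 immediate early genes were lower.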

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

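The alternatives without the genes of other cell types, without the 20 most abundant genes, without genes near Pcyt2 and Myf5, with the GC content and gene length offset, and with that offset beside the block were chosen after the data were seen. Leaving out each library in turn gave 846 to 2785 changed genes, 422 to 1337 higher, 424 to 1448 lower, 187 to 487 at least 2-fold and 14 to 21 lists, with a log2 fold change of −0.34 to −0.20 for Pcyt2 and 0.0031 to 0.29 for Myf5. The smallest counts came without Myf5Cre-Pcyt2 replicate 2. With library size alone, 3225 genes were higher and 499 lower, where the median of all genes moved by 0.21; with no filter on low counts, 629 genes reached 2-fold, as more genes were tested. With the replicate block, 1731 genes changed, 865 higher and 866 lower, and with the block and the GC content and length offset 1555, 728 and 827; the cause was not tested. With the correlation estimated per list, 0 lists passed instead of 16. The estimates for nuclear oxidative phosphorylation, slow-fibre and fast-fibre genes were 0.622, 0.707 and 0.524, far above the preset 0.01. Camera p-values with the preset correlation are therefore too small for such lists. For atrophy and denervation the estimate was −0.00726, and the unadjusted camera p still rose from 0.0018 to 0.0242. For satellite cells the estimate was 0.0475, and the unadjusted camera p rose from 1.07e-05 to 0.0225. A correlation above the preset cannot account for the rise in atrophy and denervation. The drop from 16 lists to 0 therefore does not measure correlation alone, and what else differs was not tested. Pcyt2 passed with the GC content and length offset (−0.34, adjusted p = 0.0421, range over alternatives 0.0421 to 0.706), and the cause was not tested.

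Shared calls were 2286 of the 2739 genes with DESeq2 (83.5%), 1694 with the replicate block (61.8%) and 834 without Myf5Cre-Pcyt2 replicate 2 (30.4%), all in the same direction. The 82 named genes apart from Pcyt2 and Myf5 include some with no call to lose in the main fit, such as Selenoi. Of all 82, 27 lost the call in some alternative and 22 without some library, and 0 reversed. Over all alternatives these genes lost a call 119 times and gained it 5 times, and list results lost a call 37 times, gained it 25 times and stayed on the same side and direction 666 times. The test direction reversed for 7 lists that did not pass, and the cause was not tested. A list median can differ in sign from the test direction, as for fatty acid synthesis with library size alone, where the direction was lower. With library size alone the medians were 0.27 for fatty acid synthesis, 0.18 for the proteasome and 0.18 for smooth muscle. With no filter, fatty acid synthesis had 0.0679. With the GC content and length offset, fatty acid synthesis had 0.0171, the integrated stress response −0.0355, the proteasome −0.005 and p53 −0.0066. With the replicate block and that offset, fatty acid synthesis had 0.0175, the proteasome −0.0057 and p53 −0.0257. Fry gives no median of its own, and with it the integrated stress response turned to higher (fry adjusted p = 0.89), where the main median was −0.0318. Leaving out each library in turn, medians ran from −0.0392 to 0.1077 for fatty acid synthesis, −0.1388 to −0.0121 for the integrated stress response, −0.0608 to −0.0037 for the proteasome, −0.1038 to 0.0366 for p53, −0.9247 to 0.2779 for adipocytes, −0.1038 to 0.0196 for smooth muscle and −0.0355 to 0.1956 for keratinocytes. Adipocytes reversed without control replicate 1. Depth was similar across libraries, and in simulated data 53.7% of 1.5-fold changes were recovered.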

Other observations

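All tests in this part were chosen after the results they measure were seen, the list of imprinted genes and the falls of at least 4-fold included. Of 47 tested imprinted genes, 22 rose, 1 fell and 24 did not pass, with a median log2 fold change of 0.51. Outside the fixed lists, and with Rtl1 and Zim1 left out, 14 of 36 rose, 1 fell and 21 did not pass. Zim1 (2.47-fold, adjusted p = 0.00111), Plagl1 (2.24-fold, adjusted p = 0.00165), Peg10 (2.44-fold) and Ndn (1.81-fold) rose, Snrpn was the 1 that fell (0.65-fold, adjusted p = 0.0154), and all were chosen after their values were seen. Many imprinted genes are highest in fetal and newborn tissue and fall after birth.

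The falls of at least 4-fold included transcripts close to absent in Myf5Cre-Pcyt2 libraries and abundant ones such as Actc1, at 1722 CPM. Of 25 such falls, 6 (24%) were pseudogenes, against 3.19% of tested genes and 0 of 34 rises of that size. Gm46432 had counts of 264, 217 and 114 in control and 0, 1 and 3 in Myf5Cre-Pcyt2, and Eif5al3-ps 112, 84 and 83 against 5, 3 and 5. C130080G10Rik, which lies beside Actc1 on chromosome 2, had 270, 633 and 120 against 25, 15 and 30. Gm5855 had 82, 56 and 73 against 2, 4 and 38, with replicate 3 apart as for Eno1b. These genes were chosen after their values were seen, and pseudogene reads may belong to their parent genes, so these falls would need a check by sequence.

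Several neonatal transcripts were higher and adult fibre and energy transcripts lower. A smaller share of RNA from muscle fibres would by itself raise the markers of all other cells alike. The Schwann list rose by 0.53 (SE 0.142, log2 CPM) more than the endothelial list. Both lists were picked after their medians of 0.51 and −0.06 were seen, so this difference cannot decide the question. Other medians were 0.42 for extracellular matrix, 0.30 for tendon, 0.28 for satellite cells, 0.10 for macrophages and −0.03 for smooth muscle. A smaller fibre share together with changes in the other cells, the Schwann cells among them, stays open. Bias from GC content or gene length is argued against as the whole cause of the higher developmental list by the offset, after which its median was 0.73. With the offset alone, lower genes were 44 nuclear and 4 mitochondrially encoded oxidative phosphorylation genes, against 53 and 5. Lower tricarboxylic acid cycle, glycolysis and fast-fibre genes were 17, 14 and 9, against 15, 13 and 11. The genotype, which is the difference the design names, may delay the maturation of fibres after birth. This stays untested, as does a difference between litters. Within the genotype, loss of Pcyt2 cannot be told apart from Cre driven from Myf5, which the controls are not said to carry. The fall of Actc1, a gene of fetal and newborn muscle, from 7019 to 1722 CPM would run against a delay in maturation. C130080G10Rik beside Actc1 and A530058N18Rik, whose span covers it, also fell, with log2 fold changes of −4.11 and −3.23. A change local to this locus was not tested, so Actc1 alone is weak evidence against a delay. A test of the delay would compare these libraries with control quadriceps at earlier ages.

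The Pcyt2 level differed only slightly between the groups. A swap of 2 libraries between the groups is argued against, since the 9 other splits gave at most 3 changed genes. Too few counts are argued against as the reason, as the interval of the log2 fold change reached down only to −0.52. Cells outside the Myf5 lineage and parts of the gene outside the deleted one may both contribute to the 82.3% left, and these cannot be told apart with counts per gene. Reads per exon, or a sorted muscle fraction, would test them.

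Some of the falls of at least 4-fold may come from strain sequence that differs between the groups. Sequence carried along with the Pcyt2 or Myf5 alleles is argued against as the whole cause, because 4% of the falls (1 of 25, 95% interval 0.101 to 20.4%) lay within 20 Mb of either gene, where 3.32% of tested genes lie. A weaker interferon response cannot be judged by the interferon list median of −0.43 (bootstrap SE 0.089, with genes resampled as if independent). The falls were selected for their size and the list was not, and the interferon-induced gene Xaf1 was among the falls. This cause stays open. Strain differences at other loci stay open, since counts carry no alleles. No overlap between the groups was seen for 24 of 25 falls, which the choice of called genes all but fixes, so variants in the reads would be needed.

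The imprinted list, with genes of the fixed lists, Rtl1 and Zim1 left out, kept 36 tested genes with a median of 0.37. That median was at percentile 100 of 10000 random lists matched on expression, whose 95th percentile was 0.08. Most of these values had been seen before the list was written, and the percentile describes these libraries only, so a class-wide rise of imprinted genes is a hypothesis for other litters.

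The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave the highest count in each case, 1 of the 10. It gave 2739 changed genes where the highest other gave 3, 1328 higher genes against 2, 1411 lower against 2, 410 of at least 2-fold against 3, and 16 lists against 15. The other splits passed 4 to 15 lists although they had at most 3 changed genes. Each of them held control and Myf5Cre-Pcyt2 libraries in unequal numbers on either side, so part of the group difference remained. They therefore cannot show how many lists would pass without a group difference. The count of 16 lists against 15 does not by itself set the real grouping apart.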
